A study of Homo sapiens with 18 samples.

How the data were processed

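QKI eCLIP libraries from the human embryonic stem cell line HUES6 were compared at day 0, day 4 and day 8 of cardiomyocyte differentiation. The series has 18 samples, 3 IP libraries and 3 inputs per day. Per the labels' protocols, differentiation was started with 1.5 uM CHIR and 1.5 ng/mL BMP4 and continued with 100 nM C59, and day 8 cells were collected once beating was seen at day 7 or 8. Cells were crosslinked with ultraviolet light at 400 mJ/cm2, lysates were digested with RNase I, and QKI was immunoprecipitated. RNA was taken from a membrane region of 40 to 115 kDa, and adapters with a random-mer of 10 bases were ligated, per the labels' protocols. The groups and replicate numbers came from the sample titles. No batch was stated.

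The submitters' processing notes name cutadapt, STAR and SAMtools without versions, and the hg19 build. The peak caller, the filter on duplicate reads and the mapping of repeats were not given in the sources used here. Peaks were input-normalized and on hg19, per the file headers. The deposited lists were of 2 kinds. Each IP library had its own list of clusters, called per library, and each day had 1 merged list of peaks that passed 4-fold enrichment and a 3-way IDR comparison of its libraries, per the file headers. In both kinds the authors gave a log2 fold of IP over input for each peak and a −log10 p-value of that enrichment, capped at 400. All log2 values were above 0, so only clusters above input were listed. The deposited score column was 1000 where the log2 fold and the −log10 p were both at least 3, and 200 otherwise, in every line of all lists; it was not used. No chromosome end of hg19 was exceeded by any peak. The 9 input libraries were not analysed here, and depth per library is unknown. A longer list of clusters can come from deeper sequencing, so the number of listed clusters is given beside the number of passing peaks. Intervals on shares of peaks are Wilson 95% intervals, and ratios of peak numbers have exact (Clopper-Pearson) intervals. Both cover counting error only.

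A passing peak had a fold of at least 4 and p at or below 0.001 by the authors' values. Numbers of passing peaks were compared by exact permutation tests, two-sided for pairs of days and by the F statistic over the 280 partitions into 3 days. Library similarity was the Jaccard index over nucleotides, tested over the same partitions. Overlap of reproducible peaks between days, by at least 1 nt on the same strand, was tested by two-sided Fisher's exact test against clusters of the same libraries outside the day's reproducible peaks. P-values under 1e-300 are given as that bound. Regions were the merged passing peaks of all libraries, and regions bound in 3 of 3 libraries of a day and 0 of 3 of another were counted for the real and the other splits of the 6 libraries. These tests, and the rule for named peaks, were fixed before the data were examined. The rule took, per day, the 5 reproducible peaks with the highest authors' fold that passed in 3 libraries, per pair of days and direction the 3 such peaks with no cluster of any fold in the other day, and the 3 regions with the highest lowest-of-3-days fold among those reproducible at all 3 days and passing in 9 libraries. It took 1 peak per gene, for which a locus stood in, a substitution made after the data were examined.

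The locus test was chosen after the data were examined. Reproducible peaks of the 3 lists within 20 kb on the same strand formed a locus, and loci with at least 10 reproducible peaks were tested. Passing peaks per locus and library were converted to log2 of (peaks + 0.5) over (passing peaks + 1) × 10000, and fitted with limma (lmFit, and eBayes with a variance trend) over all 9 libraries, with contrasts for the pairs of days and an F test over the 3 days, Benjamini-Hochberg adjusted at 0.05. The estimated prior degrees of freedom were infinite, so each locus took the variance of the trend and the smallest p-values rest on that model. An exact permutation test of the shares had been run first and replaced, because it recovered no locus when tested on simulated data. In 20 simulated runs with 40 of the 155 loci changed at day 0 or at day 8, the 3-day limma test recovered 8% of 2-fold, 92.9% of 4-fold and 99.9% of 8-fold changes and called 1.04% of unchanged loci in the 4-fold runs. The permutation test recovered 0% at each size. Each simulated locus changed at only 1 of the days, so partitions that kept this day together and mixed the others scored nearly as high. The 0% was thus close to fixed by the simulation and does not rank limma above the permutation test. On the real shares the permutation test called 14 loci. For day 8 against day 0, limma recovered 87.6% of 4-fold changes. Simulated loci varied between libraries by a fixed amount and may vary less than real ones. The text names the 4 loci with the smallest p per pair of days and direction, a rule also set after the data were examined, as was the choice to describe the 22q12.1 and mitochondrial loci. Folds and ratios for loci were taken on peaks summed over the 3 libraries of a day, relative to their summed passing peaks. They can differ from ratios of the mean shares and from the limma log2 differences, which use each library and a pseudocount. Against a group with no peak the fold is given as the lower limit of its exact counting interval.

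The planned tests of peak location, distance to splice sites, QKI motif share and binding of 14 fixed gene lists (346 genes), including cell type markers and QKI itself, needed an hg19 annotation or sequence and were not run. Bands came from an hg19 band table in circlize 0.4.16, whose 24 chromosome lengths matched hg19 in GenomeInfoDb 1.38.1. Gene models came from the hg19 sample of GenomicFeatures 1.54.1, with 43 of 44 gene identifiers on the main chromosomes matched to symbols. None of the 43 genes was in the fixed lists. Regions elsewhere are named by band and position. Positions are 1-based.

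No 2 libraries of a day gave the same fold at a shared position. Alternatives were an 8-fold and a p of 1e-05 threshold, no threshold, equal numbers of peaks per library (the 3030 with the smallest authors' p, then the highest fold), other overlap rules and backgrounds, the replicate number as a block, and leaving out each library. For loci, other pseudocounts, gaps, minimum numbers of peaks, windows, scalings, variance models and a covariate were added after the data were examined. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.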

Results

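QKI is an RNA-binding protein of the STAR family that recognises ACUAAY-like sequences in introns and 3′ untranslated regions and regulates splicing. Its binding was profiled by eCLIP, in which ultraviolet light links proteins to RNA in intact cells, the protein is immunoprecipitated (IP), and the attached RNA fragments are sequenced beside a size-matched input. The cells were HUES6, a human embryonic stem cell line, taken at day 0 (pluripotent cells), day 4 (cardiac progenitors) and day 8 (beating cardiomyocytes) of cardiomyocyte differentiation. Each day had 3 IP libraries, and their peak lists, scored against input by the authors, were compared here. The 9 input libraries entered only through those scores. The series title concerns QKI, the U6 tri-snRNP and weak 5′ splice sites during cardiogenesis, so the comparisons asked where QKI bound at each day and which bound positions were gained or lost between days. Read depth was unknown, because the files held peaks and no reads. The labels did not say whether the 3 libraries of a day came from separate cultures, so the spread between these libraries may be technical. Permutation p-values measured only that spread. The limma p-values took it from a trend over all loci, not from the locus's own libraries, so the smallest rest on that model. Fisher p-values counted peaks and did not measure it. Confidence intervals covered counting error only.

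Day 0 cells carried the most QKI peaks. A passing peak was enriched at least 4-fold over input with p at or below 0.001 by the authors' values. Day 0 libraries held 13757 ± 1528 passing peaks (SD, n = 3), day 4 libraries 4935 ± 2507 and day 8 libraries 7004 ± 3668. The mean at day 0 was 2.79 times that at day 4 and 1.96 times that at day 8, and the day 4 mean was 0.705 times the day 8 mean. An exact permutation test over the 280 partitions of the 9 libraries gave p = 0.0286 for the 3 days. Single pairs of days gave two-sided exact permutation p = 0.1 for day 0 against day 4 and against day 8, the smallest value 3 against 3 libraries allow, and 0.6 for day 4 against day 8 (adjusted 0.15, 0.15 and 0.6). The 3-day call ended at 8-fold enrichment (exact p = 0.0607). It also ended without day 0 replicate 1, 2 or 3 (exact p = 0.0857, 0.0607 and 0.0643), day 4 replicate 1 or 3 (0.0786 and 0.0714) or day 8 replicate 1 (0.0536). Day 0 lists were also longer before any threshold, with 156660 ± 47433 clusters per library against 77625 ± 19282 at day 4 and 58863 ± 5606 at day 8. Passing peaks made up 9.73% ± 4.73 of the clusters at day 0, 6.64% ± 3.89 at day 4 and 11.9% ± 5.68 at day 8, a difference within the spread between libraries (3-day exact permutation p = 0.439).

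**Figure D1:**
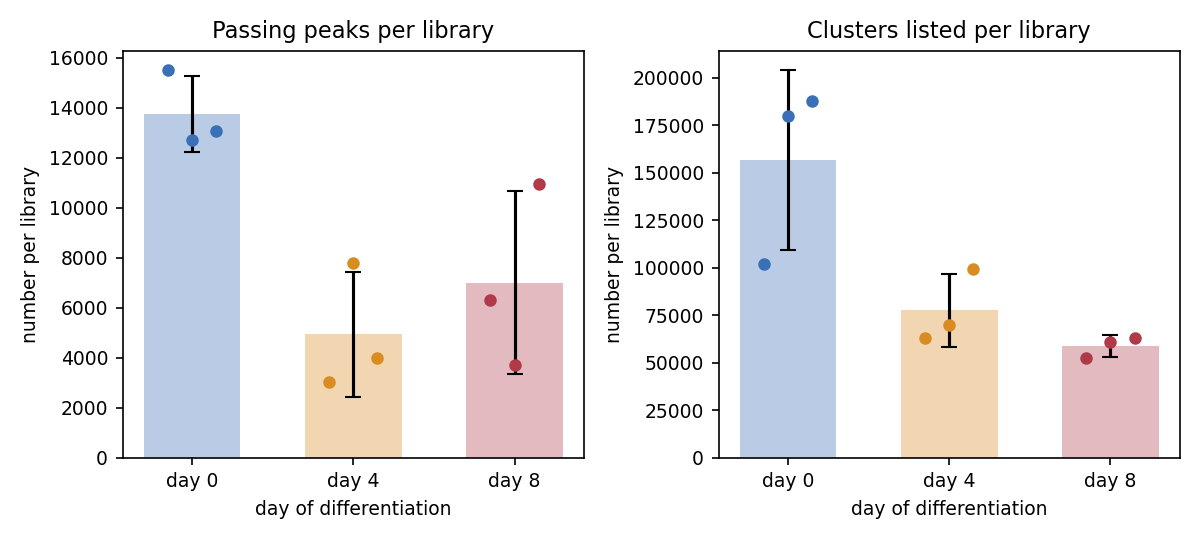
Number of passing peaks (left) and of all listed clusters (right) per library on the vertical axes, by day of differentiation. Points are the 3 libraries of a day, bars their mean and whiskers the SD, and the 3 day 0 libraries lie between 12695 and 15508 passing peaks, above every library of the other days.

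On average, libraries of the same day shared more bound positions than libraries of different days, most clearly at day 0. The Jaccard index over passing-peak nucleotides, strand by strand, averaged 0.278 within days and 0.157 between days, and the difference of 0.121 was the highest of the 280 partitions (one-sided exact permutation p = 0.00357, the smallest value possible). Day 0 libraries were the most alike, with indices of 0.376 to 0.413. Day 8 libraries reached 0.205 to 0.268, and day 4 libraries 0.125 to 0.274. Between days the index averaged 0.152 ± 0.0656 for day 0 with day 4 (SD over pairs), 0.147 ± 0.0363 for day 0 with day 8 and 0.172 ± 0.0476 for day 4 with day 8, against 0.399 ± 0.0198 within day 0, 0.197 ± 0.0746 within day 4 and 0.240 ± 0.0319 within day 8. The later days were thus not parted pair by pair. The index of day 4 replicate 2 with day 8 replicate 3, 0.255, was above 2 of the 3 day 4 pairs and 2 of the 3 day 8 pairs. Day 4 replicate 1 stood apart. Its index with day 4 replicate 2 was 0.125, below its indices of 0.136 and 0.144 with day 8 replicates 1 and 2. Its index with day 4 replicate 3 was 0.191, above those with every day 8 library (0.0848 to 0.144). It had the fewest passing peaks of all libraries, 3030.

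**Figure D2:**
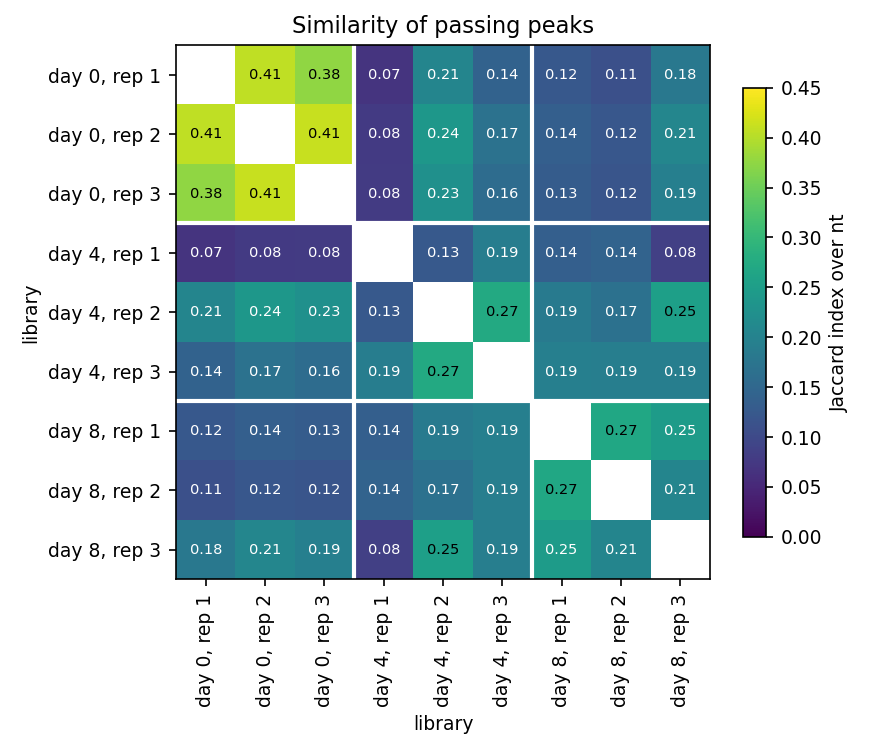
Jaccard index over nucleotides of passing peaks for each pair of the 9 libraries, with libraries on both axes and the index as colour. White lines part the days, and the day 0 block, at 0.376 to 0.413, holds the highest values.

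The authors' merged reproducible list held 7778 peaks at day 0, 947 at day 4 and 1576 at day 8. These lists pool the 3 libraries of a day and have no replicates of their own. Of their peaks, 95.4% at day 0, 94.1% at day 4 and 96.2% at day 8 overlapped a passing peak in 3 of 3 libraries of the day. Median widths were 73, 66 and 68 nt. Merging peaks that overlapped or touched left 6622, 765 and 1273 footprints, so numbers of peaks are not numbers of separate sites. Peaks on the same strand within 20 kb of each other were joined into loci, as a stand-in for genes, and this gave 3524 loci at day 0, 520 at day 4 and 708 at day 8. Of 3755 loci in all, 308 held reproducible peaks at all 3 days, 2865 at day 0 alone, 38 at day 4 alone and 163 at day 8 alone. The 10 fullest loci held 7.82% of the reproducible peaks at day 0, 16.4% at day 4 and 15.4% at day 8.

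Some of the most enriched reproducible peaks passed at every day, and others did not. At 17p11.2 a peak on the plus strand of chromosome 17 (18965361 to 18965443, hg19) passed in 9 of 9 libraries, with an authors' log2 fold over input of 10.50 at day 0, 10.72 at day 4 and 9.33 at day 8. A 360-nt region at 22q12.1 on the plus strand of chromosome 22 (27067237 to 27067596) also passed in 9 of 9 libraries, with log2 folds of 10.95, 8.26 and 9.09. At 3q11.2, on the minus strand of chromosome 3 (96327728 to 96327761), the log2 folds were 7.63, 8.40 and 9.28. These 3 led, by the lowest fold of the 3 days, the 373 regions that were reproducible at all 3 days and passed in every library. The day 0 peak with the highest log2 fold, a 3-nt peak at 22q12.1 (27068057 to 27068059, 12.11), had a cluster in only 1 of 3 day 8 libraries, and a 2-nt peak of the same locus (27069272 to 27069273, 10.15) had none at day 4 or day 8. With 1 peak taken per locus, the highest day 0 folds after 22q12.1 and 17p11.2 belonged to minus-strand 6p25.3 (9.73), plus-strand 16q12.1 (9.71) and plus-strand 5p15.33 (8.95). At day 4 the next were minus-strand 11q23.1 (9.04), plus-strand 17q21.2 (8.93) and plus-strand 6p24.2 (8.85). At day 8 a peak at 4q25 on the plus strand of chromosome 4 (109573306 to 109573319) ranked first at 9.37, and 17q21.2 was again among the first 5 (8.73). Folds describe peaks within their own list and are not compared between days here.

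Most day 4 sites were also day 0 sites. Of the day 4 reproducible peaks, 86.0% (Wilson 95% interval 83.6% to 88.0%) overlapped a day 0 reproducible peak by at least 1 nt on the same strand, and 67.7% (64.6% to 70.6%) overlapped a day 8 peak. Of the day 8 peaks, 64.7% (62.3% to 67.0%) overlapped a day 0 peak and 42.3% (39.8% to 44.7%) a day 4 peak. Of the day 0 peaks, 15.4% overlapped a day 4 peak and 17.0% a day 8 peak, shares that the shorter lists of day 4 and day 8 (947 and 1576 peaks, against 7778) keep low. When a reciprocal overlap of 50% was required, these 2 shares were 8.58% and 10.5%. Other clusters of the same libraries overlapped by at least 1 nt far less often, in 4.20% and 0.655% of cases for day 4, 5.19% and 0.477% for day 8, and 0.0619% and 0.158% for day 0. Passing peaks were a minority of all clusters, so this background was mostly weaker signal. Whether it matched the reproducible peaks in expression or mappability was not tested. Each of the 6 two-sided Fisher's exact tests gave a p at or below 1e-300, with odds ratios from 33.5 to 318. By its length the day 0 list is overlapped more easily, by background clusters too. Relative to the background, the odds ratio for day 4 peaks was 318 with day 8 and 140 with day 0. For day 8 peaks it was 153 with day 4 and 33.5 with day 0. The shares and the odds ratios thus rank the days in opposite order. Peaks are not independent replicates, so these tests describe the lists.

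More positions passed in all 3 libraries of day 0 and in none of a later day than the other way round, a difference that depended on the number of peaks per library. Merging the passing peaks of all libraries gave 29356 regions, of which 544 were bound in 9 of 9 libraries and 52.3% in 1. Day 0 held 2675 regions bound in 3 of 3 libraries and in 0 of 3 at day 4, against 77 in the opposite direction. Against day 8 these numbers were 2773 and 493. Between the later days, 522 regions were bound at day 8 and not at day 4, and 57 at day 4 and not at day 8. With the 3030 strongest peaks of each library, 376 regions were bound at day 0 and not day 4 against 230 in the opposite direction, so the difference shrank. For day 0 and day 8 its direction turned, with 495 regions bound at day 0 and not day 8 against 539. Between the later days the same setting gave 349 regions bound at day 8 and not day 4 against 136. The cut kept every passing peak of day 4 replicate 1 but dropped most of those of the day 0 libraries (12695 to 15508 each). Regions counted as absent at day 0 could thus still hold a passing peak there. The shrinkage and the turned direction are in part built in by the cut. Single libraries moved the smaller counts. Day 4 regions absent at day 0 numbered 382 without day 4 replicate 1, 148 without replicate 2 and 126 without replicate 3. Those absent at day 8 numbered 358, 118 and 116, and 160 without day 8 replicate 3. Without day 8 replicate 2, day 8 regions numbered 1057 against day 0 and 1148 against day 4, and without day 8 replicate 1 they numbered 788 against day 4.

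A stricter set of regions had no cluster of any fold in the other day. At 7q22.1, on the plus strand of chromosome 7 (99194307 to 99194400), a peak with log2 fold 7.22 passed in 3 of 3 day 8 libraries, and no cluster lay there in any day 0 or day 4 library. The same was true at 4p12 (minus strand, chromosome 4, 47637060 to 47637176), with a log2 fold of 6.65. A day 8 peak within 2q31.2 (minus strand, chromosome 2, 179622092 to 179622141, log2 fold 7.38) had no cluster at day 0 and passed in 1 of 3 day 4 libraries. Minus-strand 1p32.2 (log2 fold 6.55), 5q31.2 (6.19) and 8q24.13 (5.88) had day 4 peaks with no cluster at day 0. Day 8 peaks with no cluster at day 4 were led by a second peak at 7q22.1 (99194439 to 99194527, 7.31), plus-strand 12q24.33 (6.95) and minus-strand 4q35.1 (6.94). In this order, they passed in 2, 2 and 3 of 3 day 0 libraries. The day 0 sites without a cluster at day 8 were led by a 2-nt peak in 22q12.1 (plus strand, 27069272 to 27069273, 10.15), minus-strand 6p25.3 (8.43) and minus-strand 17q12 (8.00), and those without one at day 4 by the same 22q12.1 peak, minus-strand 9q31.3 (8.66) and plus-strand 5p15.33 (8.10). Around that 22q12.1 peak the locus still held 16 to 19 passing peaks in each day 8 library and 30 to 47 in each day 4 library. The 9q31.3 peak position passed in 3 of 3 day 8 libraries and the 5p15.33 position in 1. At day 4 the 6p25.3 position passed in 1 of 3 libraries and the 17q12 position in 2. Day 4 peaks without a cluster at day 8 lay at plus-strand 22q12.1 (6.43), minus-strand 19p13.3 (4.94) and plus-strand 16p13.2 (4.86).

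Whole loci gained and lost QKI peaks between day 0 and day 8. The clearest gain was at 2q31.2 on the minus strand of chromosome 2, where 2 neighbouring loci (179506621 to 179558861 and 179585006 to 179623624) had no passing peak in any day 0 library. The first held 58, 46 and 76 peaks in the day 8 libraries, 0.948% ± 0.272 of their passing peaks (SD, n = 3), and the second 21, 17 and 28. Their shares at day 8 were higher than at day 0 (limma adjusted p = 1.97e-58 and 8.43e-31). The lower limits of the exact counting intervals, marked as at least from here on, were 94.9-fold and 34.2-fold. A 1033-nt locus at 11p15.3 (plus strand, chromosome 11, 12284050 to 12285082) rose from 1 peak over the 3 day 0 libraries to 7, 9 and 7 peaks at day 8, a ratio of 45.2 with an exact counting interval of 7.34 to 1861 (log2 difference 4.60 ± 0.54 SE, limma adjusted p = 1.61e-15). Plus-strand 4q22.3 (95502992 to 95541250) rose from a mean share of 0.0125% ± 0.00525 of passing peaks to 0.264% ± 0.0609, and 20-fold on summed peaks (limma adjusted p = 4.66e-13). In the opposite direction, 3p12.3 on the plus strand of chromosome 3 (76198522 to 76287701) held 35, 39 and 26 peaks at day 0 and none at day 4 or day 8. Its share was at least 13.5-fold lower at day 8 (limma adjusted p = 2.57e-17). A neighbouring 3p12.3 locus (75993511 to 76072287) fell at least 8.58-fold. On the plus strand of chromosome 4, the locus at 4q22.1-q22.2 (93645655 to 93711539) held 35 peaks in each day 0 library and 1 peak over the 3 day 8 libraries (log2 difference -4.52 ± 0.50, limma adjusted p = 2.7e-17). On the same strand, 4q22.1 (93518771 to 93622483) fell at least 9.55-fold. Clusters of any fold were also nearly gone at these lost loci. Per library the 3p12.3 loci held 95 to 141 and 94 to 116 at day 0 and 0 at day 8. The 4q22.1-q22.2 and 4q22.1 loci held 94 to 129 and 88 to 165 at day 0, and 0 to 2 each at day 8. Here and at the loci named below, a change in RNA level was not told apart from a change in binding.

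Of 155 loci with at least 10 reproducible peaks, 25 had a higher share of passing peaks at day 8 than at day 0, 32 a lower one and 98 did not pass limma with Benjamini-Hochberg adjustment. These loci were chosen by reproducible peaks called from the same libraries, 7778 at day 0, 947 at day 4 and 1576 at day 8. The choice favours loci with many peaks at 1 day, mostly day 0. Counts of directions, here and below, thus do not estimate the balance over all bound loci. The median locus moved by 0.08 on the log2 scale. The balance of directions depended on the setting and on single libraries: with equal numbers of peaks 27 loci were higher and 77 lower (median shift -0.69), or 43 and 44 when these were centred on the median locus, and with the number of passing peaks as a covariate 12 were higher and 45 lower (median shift -0.55). Other settings tilted the balance the other way, with 33 higher and 27 lower at pseudocount 2, 33 and 30 by covered nucleotides, 23 and 19 with peaks joined within 5 kb, and 8 and 5 among loci of at least 20 peaks. Without day 8 replicate 3, 41 loci were higher and 31 lower (median shift 0.38), and without day 8 replicate 2, 17 were higher and 39 lower (median shift -0.23).

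**Figure D3:**
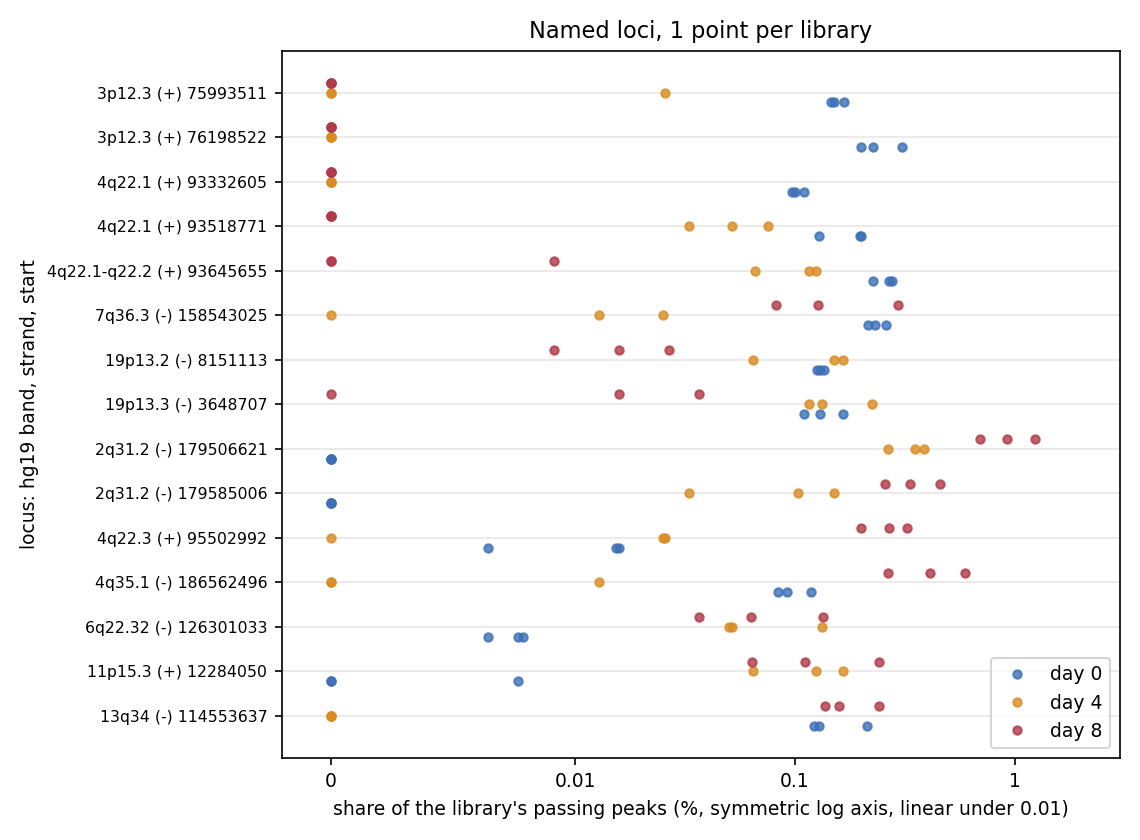
Share of each library's passing peaks in the loci named for pairs of days, on a symmetric log axis in percent that is linear under 0.01, with loci listed by hg19 band, strand and start. Each point is 1 library coloured by day, and at 2q31.2 the 3 day 0 libraries lie at 0 while day 8 averages 0.948% and 0.348%.

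**Figure D4:**
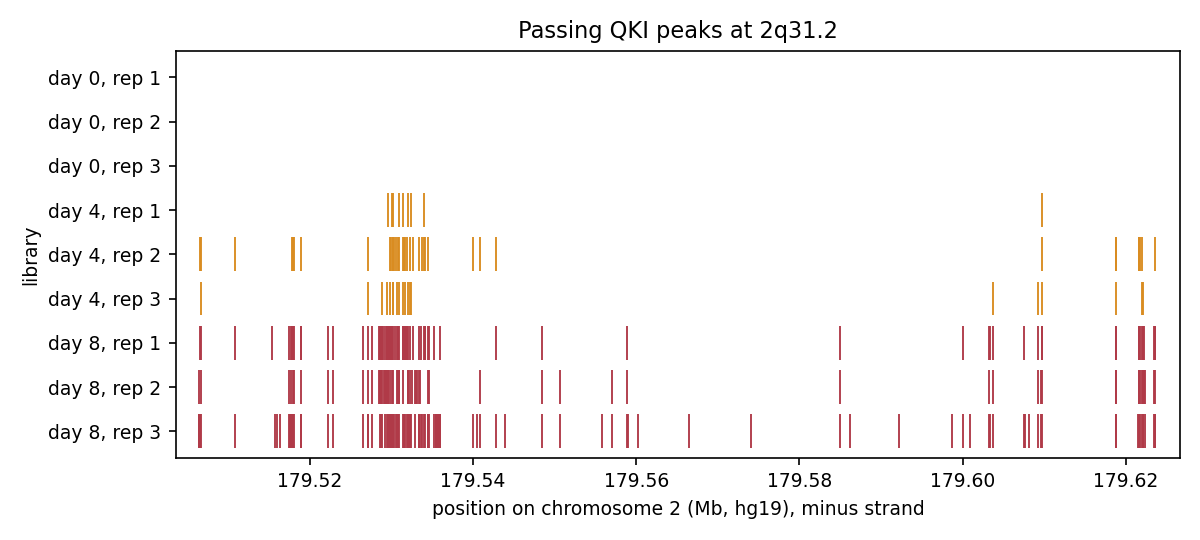
Midpoints of passing peaks on the minus strand of chromosome 2 across the 2q31.2 loci, by hg19 position in Mb, with 1 row per library coloured by day. Rows of day 0 are empty, and day 8 rows are the densest.

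By day 4 the 2q31.2 loci had already gained peaks. The first held 8, 30 and 14 peaks in the day 4 libraries and the second 1, 8 and 6. Their shares were at least 37.9-fold and at least 10.0-fold higher than at day 0 (limma adjusted p = 6.75e-41 and 2.51e-16). Their log2 differences were 6.55 and 4.71. With equal numbers of peaks these shrank to 4.69 and 2.11 (limma adjusted p = 1.62e-06 and 0.00299). At 11p15.3 there were 5 peaks in each day 4 library (ratio 41.8, exact counting interval 6.43 to 1760, limma adjusted p = 8.32e-15). A 48-nt locus at 6q22.32 (minus strand, chromosome 6, 126301033 to 126301080) rose from 1 peak in each day 0 library to 4, 4 and 2 peaks, a ratio of 9.29 (interval 2.39 to 52.5, limma adjusted p = 1.21e-06, log2 difference 2.89 ± 0.54). Peaks so close together are not separate sites, and every day 0 library already had a peak there. By covered nucleotides the log2 difference was 1.82 (limma adjusted p = 0.019). With the number of passing peaks as a covariate this call ended, at a log2 difference of 1.26 (limma adjusted p = 0.0992, the highest of 19 alternatives, the lowest being 8.95e-09). The losses with the smallest p-values were at 3p12.3 (76198522 to 76287701), 13q34 (minus strand, chromosome 13, 114553637 to 114564979), 7q36.3 (minus strand, chromosome 7, 158543025 to 158575873) and 4q22.1 (plus strand, chromosome 4, 93332605 to 93382835). The share fell at least 9.55-fold at 3p12.3 and at least 3.91-fold at 4q22.1. At 7q36.3 the day 0 libraries held 36, 33 and 28 peaks and the day 4 libraries 0, 1 and 1 (log2 difference -3.38 ± 0.46, limma adjusted p = 1.29e-11). At 13q34 the share fell at least 5.95-fold (log2 difference -3.80 ± 0.50, limma adjusted p = 2.26e-12). With equal numbers of peaks the log2 difference there was -0.53 (limma adjusted p = 0.258), and with these libraries also centred on the median locus it was 0.41 (adjusted p = 0.432, the highest of 19 alternatives, the lowest being 5.42e-15), so this call depended on the setting. Over all 155 loci, 23 were higher at day 4 than at day 0, 27 were lower and 105 did not pass, with a median shift of 0.14. Without day 4 replicate 1, 28 loci passed, and without day 0 replicate 2, 31 loci passed. Equal numbers of peaks gave 15 higher and 80 lower (median shift -0.90), or 39 and 41 when centred on the median locus, and the covariate 3 higher and 33 lower (median shift -0.84). More loci were higher than lower at pseudocount 2 (30 and 10), by covered nucleotides (36 and 22, median shift 0.51), at p 1e-05 (39 and 28) and with peaks joined within 5 kb (22 and 13). Without day 4 replicate 3, 14 were higher and 27 lower.

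Between day 4 and day 8, 13 loci were higher at day 8, 13 were lower and 129 did not pass. The gain with the smallest p-value was at 4q35.1 on the minus strand of chromosome 4 (186562496 to 186606115), which held 26, 22 and 29 peaks at day 8, 1 peak over the 3 day 4 libraries, and 13, 15 and 12 peaks at day 0. On peaks summed over libraries, as for the other folds and ratios here, the day 8 share was 54.3 times the day 4 share (exact counting interval 9.45 to 2170). The limma log2 difference, from single libraries with a pseudocount, was 4.69 ± 0.47 (limma adjusted p = 4.1e-20). The 13q34 locus was at least 6.15-fold higher at day 8 than at day 4 (limma adjusted p = 1.51e-13). At 7q36.3 the day 8 share was 9.86 times the day 4 share (exact counting interval 2.49 to 85.4, limma adjusted p = 1.19e-07). Plus-strand 4q22.3 rose 12-fold (limma adjusted p = 3.27e-08). The 4q22.1-q22.2 locus fell further, with a log2 difference of -3.30 ± 0.50, and 4q22.1 (93518771 to 93622483) fell at least 2.42-fold. A pair of minus-strand loci on chromosome 19 kept their share at day 4 close to day 0 and fell at day 8. The locus at 19p13.3 (3648707 to 3651762) averaged 0.158% ± 0.0590 of passing peaks at day 4 and 0.0174% ± 0.0183 at day 8 (limma adjusted p = 2.03e-07), and that at 19p13.2 (8151113 to 8162050) fell 7.57-fold (adjusted p = 1.14e-05). The median log2 shift was -0.24, and equal numbers of peaks gave 32 higher and 13 lower, or 32 and 22 when centred, and the covariate 31 and 16. The opposite balance came with p 1e-05 (18 higher and 32 lower) and median centring (22 and 33). Without day 8 replicate 2, 52 loci passed, 13 higher and 39 lower. Without day 8 replicate 3 the numbers were 23 and 11, and without day 4 replicate 3, 15 and 8.

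Over the 3 days together, 69 of the 155 loci changed by limma, with the highest share at day 0 in 30, at day 4 in 12 and at day 8 in 27. The locus test was chosen after the data were examined. An exact permutation test of the same shares, run before it, called 14 loci, 12 of them among the 69. Of the loci named above it called the 2 at 2q31.2, 4q22.1 (93518771 to 93622483), 4q22.1-q22.2 and 4q35.1 (adjusted p = 0.0395 each). The other named loci had adjusted permutation p-values of 0.103 to 0.259. At 3p12.3 (76198522 to 76287701) and 4q22.1 (93332605 to 93382835) no day 4 or day 8 library held a passing peak. Partitions that keep the day 0 libraries together then tie, so the permutation test could not reach its smallest p there. Its adjusted p of 0.115 at these loci does not weigh against the losses. In the named loci the limma calls kept their direction and their side of the threshold in 19 alternatives, except at 6q22.32 and 13q34 between day 0 and day 4, as given above. The named loci had the smallest p-values in the same data, so this is a weak check. Some alternatives left out a library of the day not compared, which leaves the log2 difference unchanged. Other gaps, minimum numbers of peaks and windows were not among the 19.

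The locus with the most reproducible peaks over the 3 lists together was at 22q12.1 on the plus strand of chromosome 22 (27065918 to 27070593, 4676 nt). It held 239 reproducible peaks at day 0, 34 at day 4 and 10 at day 8. Day 0 libraries had 235 ± 5.03 passing peaks there (SD, n = 3), day 4 libraries 38.3 ± 8.50 and day 8 libraries 17.0 ± 1.73. As a share of all passing peaks this was 1.73% ± 0.215, 0.885% ± 0.355 and 0.303% ± 0.187. The log2 difference between day 8 and day 0 was -2.65 ± 0.49 (limma adjusted p = 6.1e-07), and that between day 4 and day 0 was -1.04 ± 0.49 (adjusted p = 0.0891). A locus on the plus strand of the mitochondrial genome (619 to 15947) held 76.0 ± 12.5, 45.3 ± 3.51 and 57.7 ± 27.4 passing peaks per library at days 0, 4 and 8, and its share did not pass over the 3 days (limma adjusted p = 0.291).

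**Figure D5:**
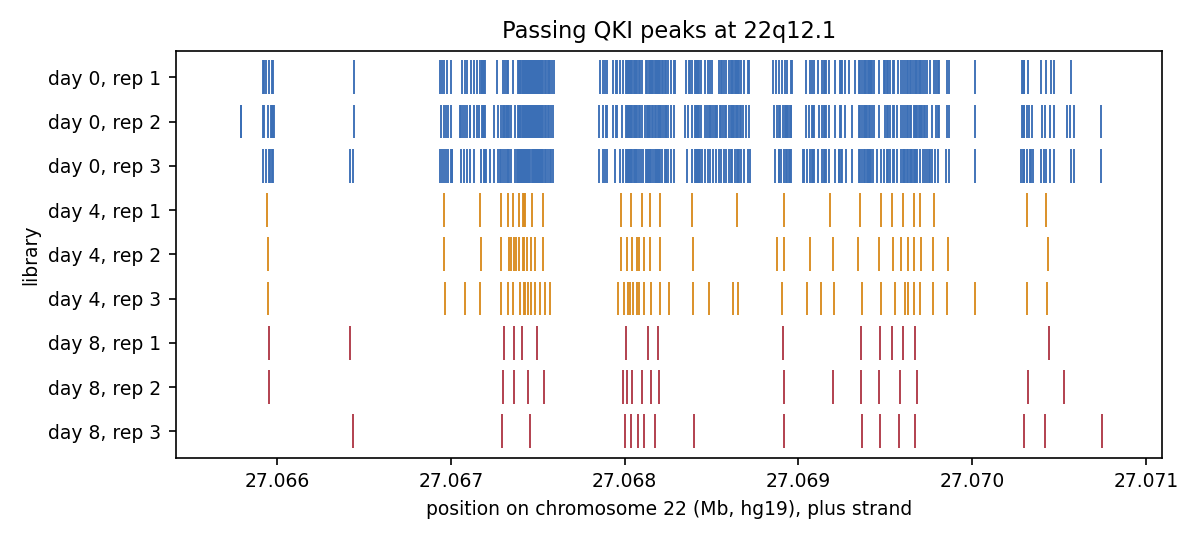
Midpoints of passing peaks on the plus strand of chromosome 22 across the 22q12.1 locus, by hg19 position in Mb, with 1 row per library coloured by day. The day 0 libraries hold 230 to 240 peaks in the locus, the day 4 libraries 30 to 47 and the day 8 libraries 16 to 19.

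Gene models in the hg19 build were at hand for 43 genes only, a sample distributed with an R package and chosen without regard to QKI. Reproducible peaks lay in 8 of these genes at day 0, 1 at day 4 and 2 at day 8, and 31 genes had no passing peak in any library. All 19 reproducible peaks in them were intronic. SRPK1, which encodes a kinase of SR splicing factors, carried 6 reproducible peaks at day 0, 1 at day 4 and 1 at day 8. Its peak on the minus strand of chromosome 6 near 35849841 was found at all 3 days, about 4600 nt after a 5′ splice site, with authors' log2 folds of 6.20, 5.83 and 6.18. The day 0 libraries held 10, 7 and 7 passing peaks in SRPK1, the day 4 libraries 2, 7 and 3 and the day 8 libraries 3, 2 and 7. Within the gene model of SARS2, the mitochondrial seryl-tRNA synthetase gene, lay 3 reproducible peaks at day 0. They lay 109, 245 and 995 nt before a 3′ splice site, in an intron of a long listed transcript. With models for 43 genes only, whether these peaks belong to another gene at the same position could not be checked. The 3 day 0 libraries held 6, 6 and 3 passing peaks within this model and the 6 later libraries none. SKA3, a gene of the spindle and kinetochore, had 2 reproducible peaks at day 0 and no passing peak at day 4 or day 8. In RIF1, a regulator of replication timing and DNA repair, the day 0 peak on chromosome 2 (152308279 to 152308363) was centred 102 nt after a 5′ splice site. FAM199X was bound in 1 intron at day 0 and day 8, at log2 folds of 4.71 and 4.36. ATF7IP2, R3HDM1 and ZNF107 each held 1 reproducible peak, at day 0.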

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

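Alternatives for loci, for the plus-strand share and for the named reproducible peaks were chosen after the data were examined, the others before. Similarity within days stayed above that between days (p at most 0.05) in each of 14 alternatives, and the 24 overlap alternatives kept their direction and side of the threshold. At a reciprocal overlap of 50% the shares of day 0 peaks found at day 4 and day 8 fell from 15.4% and 17.0% to 8.58% and 10.5%. Reproducible peaks of at least 8-fold numbered 7233, 859 and 1475 at days 0, 4 and 8, and regions passing in all 3 libraries 5954, 999 and 1832. The 3-day p for passing peaks rose to 0.0607 at 8-fold and to 0.111 with the replicate number as a block. It lay at 0.0179 to 0.0857 with single libraries left out. It was above 0.05 without any 1 of the day 0 libraries, day 4 replicates 1 or 3, or day 8 replicate 1; the smaller number of samples is part of the cause. Without a threshold the day 4 to day 8 ratio was 1.32. The same-number correlations of deviations ran from -0.0638 to 0.105, and 8 of 18 comparisons were best with the own number. Under the replicate block 63 loci changed over 3 days, against 69, and the similarity test and the pairs of loci counts kept within 1.5 times.

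Regions bound in 3 of 3 against 0 of 3 moved with the number of peaks. Equal numbers gave 376 and 230 (day 0 and day 4), 495 for day 0 not day 8, and 136 for day 4 not day 8. This cut dropped passing peaks of the longer lists, so part of the move is by construction. Absence of any cluster gave 1220 and 28 (day 0 and day 4), 1490 and 294 (day 0 and day 8), and 11 and 278 (day 4 and day 8). A p of 1e-05 gave 43 day 4 regions absent at day 0 and 35 absent at day 8. Leaving out single libraries gave 77 to 382 and 57 to 358 for those, 493 to 1057 for day 8 not day 0, and 522 to 1148 for day 8 not day 4. With a library left out, 2 libraries of its day suffice in place of 3, which adds regions by construction.

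Loci changed over 3 days numbered 116 with equal numbers of peaks, 105 when these were also centred on the median locus, 239 and 17 with at least 5 and 20 reproducible peaks, 389 of 921 in 100-kb windows and 14 by the permutation test. For day 4 against day 0 the same settings gave 95, 80, 169, 11 and 241, for day 8 against day 0 104, 87, 207, 13 and 346, and for day 8 against day 4 45, 54, 89, 11 and 156. The last also moved to 16 at 8-fold, 50 at p 1e-05, 47 with the covariate, 55 after median centring, 15 with pseudocount 2, and 17 and 51 with gaps of 5 and 50 kb. More or fewer loci tested explains the changes with minimum peaks, gaps and windows in part; otherwise the cause was not tested. The loss at 13q34 between day 0 and day 4 (log2 -3.80) reversed to 0.41 with equal numbers centred on the median locus, without passing the threshold (adjusted p = 0.432), and the cause was not tested. Leaving out single libraries gave 28 to 65 (day 4 against day 0; lowest without day 4 replicate 1) and 18 to 52 (day 8 against day 4; highest without day 8 replicate 2). Peak location, splice-site distance, motif share and gene list binding, with their alternatives, were not run. Unknown depth limits any statement that a position without a cluster was unbound.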

Other observations

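The splits for regions bound in 3 libraries were planned before the data were examined, and the other tests in this part were chosen after the results were seen. The mean share of passing peaks on the plus strand was 55.6% ± 0.278 at day 0, 53.4% ± 0.875 at day 4 and 52.0% ± 0.710 at day 8 (SD, n = 3, 3-day exact permutation p = 0.00714). The test does not ask for an order of days, and day 4 replicate 2 (52.5%) lay below day 8 replicate 2 (52.8%). In the reproducible lists the share was 56.9%, 59.7% and 54.8%, so it was higher at day 4 than at day 0 there. Mitochondrial peaks lay on the plus strand in 90.3% to 96.5% of cases in each library, with no difference between days past the threshold (exact permutation p = 0.346). Chromosome 2 held 6.77% ± 0.113 of passing peaks at day 0, 7.15% ± 1.16 at day 4 and 10.7% ± 0.302 at day 8 (exact permutation p = 0.025, adjusted 0.129 over 24 chromosomes, none of which passed, 8 being under 0.05 unadjusted). Without the 2q31.2 loci chromosome 2 still held 9.52% ± 0.226 at day 8, against 6.77% at day 0 (exact permutation p = 0.0357).

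Chance assignment of libraries to days was examined by other splits. Over 100 drawn splits into 3 days, the real one included, 2 called at least the 69 loci of the real one, which argues against a chance assignment, but the highest other split called 75. That split kept the day 0 libraries together and parted the remaining libraries into those with more and those with fewer passing peaks, which points to a structure of the samples beyond the day. With the day 0 libraries together, the 4 other drawn splits called 29 to 75 loci, and with them apart at most 13. For pairs of days only 10 splits exist, too few for a share under 0.05. The real split was in each case the 1 with the most: 50 loci for day 0 and day 4, 57 for day 0 and day 8 and 26 for day 4 and day 8, against 0 in all others. For regions bound in 3 libraries against 0, both directions together, the real splits gave 2752, 3266 and 579 and the highest others 233, 256 and 450.

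The locus changes could reflect the number of passing peaks per library rather than the day, since every day 0 library had more passing peaks than any later one. With equal numbers of peaks per library, centred on the median locus, 25 of the 25 loci higher at day 8 than at day 0 kept their call and 30 of the 32 lower ones. Between day 4 and day 8, 13 of 13 higher and 11 of 13 lower loci kept it, and 25 of the 27 loci lower at day 4 than at day 0. Centring removes a shift common to all loci, so this setting alone does not settle the question. Without centring, equal numbers kept 19 of 25, 32 of 32, 13 of 13, 9 of 13 and 25 of 27. Of the loci higher at day 4 than at day 0, 19 of 23 kept their call with equal numbers and centring, 10 with equal numbers alone and 3 with the number of passing peaks as a covariate. For these the day and the number of peaks cannot be told apart, because the answer turns on the scaling. With the covariate, 16 of 27 loci lower at day 4, and 12 of 25 higher and 27 of 32 lower at day 8 against day 0, stayed past the threshold. For the loci lower at day 4 and those higher at day 8 than at day 0, the answer thus also turned on the setting. There too the day and the number of peaks cannot be told apart. Of all calls between day 8 and day 0, 55 of 57 had the same sign with it, at a median 0.838 times the log2 size. Of those between day 4 and day 0, 45 of 50 had the same sign, at 0.689 times. Between day 4 and day 8 the covariate kept 13 of 13 in each direction. The loci lower at day 8 than at day 0, and both sets between day 4 and day 8, kept most calls in each of these settings. For these sets the values argue against the number of peaks as the whole cause. Sequencing depth is unknown and stays open.

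Gain of peaks at 2q31.2 was the largest change among the 155 tested loci between day 0 and day 8, with log2 differences of 7.99 and 6.57. Longer lists at day 8 are argued against, since day 8 libraries held 0.509 times the passing peaks of day 0 libraries. Little RNA from the locus in day 0 cells is a candidate explanation. Clusters of any fold numbered at most 7 over both loci in a day 0 library, against at least 97 in a day 8 library and 48 to 77 at day 4. RNA that was present and unbound could have left background clusters, but only clusters above input were listed, so a change in QKI binding at a constant RNA level stays open without RNA-seq. Stage of differentiation stays open as the origin of either.

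Day 4 replicate 1 stood apart from the other day 4 libraries. Its low number of peaks may contribute, but with 3030 peaks in each library its Jaccard index with day 4 replicate 2 was still 0.563 times that of replicates 2 and 3 (0.207 against 0.368). At these equal numbers its indices with both other day 4 libraries (0.207 and 0.217) were above its highest with a day 8 library (0.168). A day 8 library under a day 4 label is argued against, because 0.297% of its passing peaks lay at 2q31.2, below the 0.948% of the lowest day 8 library. A day 0 library is argued against by the same peaks, of which day 0 libraries had none. Input quality and culture differences stay open and were not tested.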
